A study of Homo sapiens with 6 samples.

How the data were processed

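Per the labels, U87MG cells transfected with control siRNA were kept at 21% or 1% oxygen for 24 hours, RNA was extracted after ribosome density fractionation, and libraries for mRNA sequencing were constructed by Exiqon. Each of the 6 libraries was assigned to its oxygen condition and fraction from its labels, and each column of the table was matched to a library by its name. The authors deposited FPKM values per assembled locus, a unit taken from the name of their table in the labels and from the values. The aligner, genome build, annotation and quantification tool are not given in the sources used here.

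The digits of the values were examined for further processing. The normoxia free/monosome column held values of at most 6 significant digits. Each of the other 5 columns became 6-digit numbers, for 100% of its values within a tolerance of 0.01 in the last digit, when divided by 1 factor. These factors were 3.87 for normoxia oligosome, 2.75 for normoxia polysome, 1.96 for hypoxia free/monosome, 2.67 for hypoxia oligosome and 3.61 for hypoxia polysome. The deposited FPKM had thus been multiplied by a factor per library, and what the factors stand for is not given in the sources used here. Without them the median FPKM lay between 13.8 and 14.6 in all 6 libraries. Every locus had at least 1 library above 5 FPKM before the factor, the lowest such maximum being 5.01. The loci stood in order of TE difference. Values listed at 0 numbered 38 in normoxia oligosome, 105 in hypoxia oligosome and 235 in hypoxia polysome, and 0 in the other libraries, so a value of 0 can be a failed estimate. No TE difference of a single locus is given where polysome or free/monosome was listed at 0, but such loci stay in sums over fractions, in counts and in list medians. The 10 loci with the highest values held between 8.17% and 25.9% of a library's FPKM sum. Loci without a gene name, 717 in number, held 10.9% of the sum in normoxia free/monosome and stayed out of the comparisons. A locus can carry several gene names, as 1449 did, and its value then belongs to all of them, which the text calls a shared locus. No depth or counts were used, so no interval is given.

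From the deposited values, mRNA was compared as log2 of (hypoxia sum + 0.5) over (normoxia sum + 0.5), where each sum runs over the 3 fractions. TE was log2 of (polysome + 0.5) over (free/monosome + 0.5), and its difference was hypoxia minus normoxia. Fold differences are thus on the log2(value + pseudocount) scale, with a pseudocount of 0.5 FPKM, and are understated for low genes. Loci needed a mean of at least 5 FPKM over the 6 libraries, which 10973 named loci had. With 1 library per group no test across samples was run, and loci were counted past a size of 2-fold.

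For 25 gene lists, chosen by textbook function and matched by symbol or older symbol, the median was placed among the medians of 10000 random lists of the same size, matched over 20 bins of mean FPKM. This percentile is a description of these libraries, not a p-value, and lists with under 5 measured genes have values only. A list was taken to stand apart outside the central 95% of random medians. The named genes followed a rule. For mRNA they were the 10 highest and 10 lowest loci with a mean of at least 10 FPKM and the same sign in all 3 fraction pairs. For TE they were the 10 highest and lowest with a mean of at least 10 FPKM over the 4 libraries used and the same sign when oligosome values were added to polysome values. To these came the 3 genes with the greatest difference in each list, all genes of the glycolysis, oxygen sensing and iron handling lists, and a set of hypoxia, translation and reference genes. Other genes named as examples of a list were chosen after their values were seen. Some genes that the rule takes are not reported here. Lists, rule, thresholds and most alternatives were fixed before the data were examined.

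Coding length was the longest coding sequence per symbol in GENCODE 29, and 80.9% of tested loci had one, 59 of them through the listed gene of a shared locus. It was used for length only, never for coordinates. Random lists matched on mean FPKM and on coding length used 10 bins of length crossed with 10 bins of mean. In both kinds of matching, random lists were drawn from all loci of a bin, the listed genes included. Alternatives fixed in advance covered the pseudocount, the filter on low values, the scaling of libraries, the fractions summed, the definition of TE and the size threshold. Chosen after the data were seen were dividing out the library factors, loci with 1 protein-coding gene name, loci above 0 in every library, mRNA from the oligosome libraries alone, and matching on coding length.

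The code was tested on simulated data with 10973 loci, a noise SD of 0.2 log2 and 200 loci changed 4-fold in each measure. It put 100% of those changed in mRNA and 99.5% of those changed in TE past 2-fold in the right direction. Of 10573 unchanged loci 0 passed in mRNA and 2 in TE. The noise was set by hand and not estimated from these libraries, so these counts give no rate of false calls for them. A list of 30 with 20 changed genes reached percentile 100, and 5 of 100 unchanged lists fell outside the central 95%. Of 3 simulated library factors, 3 were recovered. Calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.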

Results

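The libraries came from U87MG, an established human glioblastoma cell line, transfected with a control siRNA and kept for 24 hours at 21% oxygen (normoxia) or 1% oxygen (hypoxia). Cell extracts were separated by ribosome density, and mRNA from 3 pooled fractions was sequenced. The free/monosome fraction holds mRNAs with no ribosome or a single one, the oligosome fraction those with a few, and the polysome fraction those with many. This gave 6 libraries, 1 for each oxygen condition and fraction. There are no replicates, so no p-value or error is given, and every difference is a description of these libraries. The table held FPKM values for 11844 loci, of which 11127 had a gene name, and 10973 named loci with a mean of at least 5 FPKM were compared. Median FPKM as deposited was 14.4, 53.3 and 38.4 in the normoxia free/monosome, oligosome and polysome libraries and 27.8, 37.3 and 52.8 in the hypoxia ones. Read depth is unknown, because only FPKM values were used.

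Steady-state mRNA was taken as the sum over the 3 fractions of a condition, and translation efficiency (TE) as polysome over free/monosome abundance, the definitions in the series' design text. The question was how 24 hours of low oxygen altered the amount of each mRNA and its ratio of polysome to free/monosome abundance. The median locus had a log2 hypoxia over normoxia of 0.20 for mRNA and −0.53 for TE, and with the authors' library factors divided out these medians were 0.06 and 0.01. Log2 differences of genes and medians of gene lists are therefore given relative to the median locus, hypoxia against normoxia, unless another scale is named.

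Hypoxic cells held far more mRNA of glycolysis, of other targets of the hypoxia-inducible factors (HIF) and of the extracellular matrix. They held less mRNA of the amino acid stress response and of DNA replication. F3, which encodes tissue factor, the starter of blood clotting, stood at a summed 26.1 FPKM in normoxia and 3477 FPKM in hypoxia, a relative log2 difference of 6.84. IGFBP3, a binding protein of insulin-like growth factors, went from 44.1 to 4878 FPKM (6.58), and LOX, the collagen cross-linking lysyl oxidase, from 89.0 to 3116 FPKM (4.93). At the other end, PSAT1, an enzyme of serine synthesis, stood at 748 FPKM in normoxia and 86.3 FPKM in hypoxia (−3.30).

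The glycolysis list held 20 genes, all measured. Relative to the median locus 17 were at least 2-fold higher in hypoxia and 0 were lower, with a list median of 1.71 (percentile 100 among 10000 random lists matched on mean FPKM). The glucose transporter SLC2A1 (locus XLOC_003806, chromosome 1, 43391062 to 43424530; here and for the other loci the build is not given in the sources used here) was higher by 3.26. The aldolase ALDOC was higher by 3.05, the first enzyme of the pathway, HK2, by 3.03, and PGK1 by 2.86. LDHA, which makes lactate, was at 1.93, GAPDH at 1.55 and ALDOA at 1.59. PFKM (0.79), PGAM1 (0.83) and HK1 (0.95) lay short of 2-fold.

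Among HIF targets outside glycolysis, 30 of 32 measured genes were at least 2-fold higher and 0 lower, with a median of 2.42 (percentile 100). After LOX (XLOC_049723, chromosome 5, 121297656 to 121413980) the highest were ANGPTL4, a secreted inhibitor of lipoprotein lipase (4.34), HILPDA, a lipid droplet protein read from a locus shared with METTL2B (3.92), and the stress-responsive NDRG1 (3.86; XLOC_060015, chromosome 8, 134249387 to 134314265). The carbonic anhydrase CA9 (XLOC_060520, chromosome 9, 35658301 to 35681156) was at 2.67 and the angiogenic factor VEGFA at 2.15. The histone demethylase gene KDM4B (0.52) and WSB1 (0.93) lay under 2-fold.

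Oxygen sensing genes had a median of 0.86 (percentile 99.98), with 5 of 13 at least 2-fold higher. EGLN1, the prolyl hydroxylase that marks HIF for destruction, was at 1.61, KDM5B at 1.30 and the HIF regulator gene CITED2 at 1.15. EGLN2, in a locus shared with other genes, was lower at −1.11. HIF1A, also in a shared locus, was at 0.86 and ARNT at 0.89. EPAS1, which encodes HIF-2α, was at 0.10, and its sign turned when the libraries were given the same median or upper quartile or when the library factors were divided out.

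Matrix genes were higher in 15 of 21 cases by at least 2-fold and lower in 1, with a median of 1.30 (percentile 100). The highest were TGFBI (3.27), a matrix adhesion protein, and the collagen genes COL5A1 (2.77) and COL1A2 (2.67), while the laminin gene LAMA4 was lower (−1.05). A list of chaperones and folding genes of the endoplasmic reticulum (ER) had a median of 0.61 (percentile 99.9). It also holds HERPUD1, SEC61B and XBP1, which are not chaperone genes. Of its 20 members 6 were at least 2-fold higher, led by HSP90B1 (1.77, in a locus shared with MIR3652), CALR (1.60) and HSPA5 (1.59). Without the oligosome or the polysome fraction this list lay inside the central 95% (percentiles 97.4 and 94.8). Glioma and neural progenitor markers were measured for 9 of 20 genes and 5 were at least 2-fold higher, with a median of 1.32 (percentile 99.98). These included EGFR (2.05), VIM (1.61) and CD109 (1.59), and FABP7 was at −0.46. SOX2, NES, GFAP, OLIG2 and PROM1 were among the markers not measured, so the list median does not describe them. Of the markers of neurons, microglia, endothelium and blood, 4 of 22 were measured: SNAP25 (0.89), MAP2 (0.33), CSF1R (0.12) and CD68, in a locus shared with EIF4A1 (0.14).

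The target list of ATF4, the transcription factor of the amino acid stress response, was the lowest. Of 24 genes 12 were at least 2-fold lower and 1 higher, with a median of −0.87 (percentile 0). CHAC1, which degrades glutathione, was lowest (−4.26; 54.5 FPKM in normoxia and 2.78 FPKM in hypoxia). The cystine transporter gene SLC7A11 was at −2.75, the pseudokinase gene TRIB3 at −2.21 and asparagine synthetase, ASNS, at −1.24. VLDLR, which HIF also regulates, was higher (1.32), and ATF4 itself was at −0.56. DNA replication and mitosis genes had a median of −0.72 (percentile 0), with 10 of 34 at least 2-fold lower and 0 higher. GINS2 (−1.62) and RFC4 (−1.36) serve at the replication fork, and BIRC5 (−1.42) encodes survivin. Heat shock genes had a median of −0.43 (percentile 1.03), with HSPE1 at −1.37 and HSPA4 at −0.86, and lay inside the central 95% without the free/monosome fraction (percentile 17.6).

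Nuclear genes of oxidative phosphorylation had a median of −0.26 (percentile 0.01), which ran from −0.58 to 0.02 over the alternatives and stayed outside the central 95% of random lists in each. At least 2-fold lower were 9 of 71, among them NDUFS6 (−1.80), ATP5MC1 (−1.51) and NDUFS8 (−1.44, shared with MIR4691), and 0 were higher. Mitochondrial ribosomal protein genes had a median of −0.31 (percentile 0.03), with 9 of 72 lower, such as MRPL41 (−1.65), and 1 higher, MRPS6, which shares a locus with SLC5A3. Without the polysome fraction that list was at percentile 19.6. Cytosolic ribosomal protein genes had a median of 0.38 (percentile 99.2), led by RPL12 (1.07). That list turned to percentile 28.8 with every library at the same median, 7.02 with the same upper quartile and 16.7 with the library factors divided out. Without the free/monosome fraction its median was −0.48.

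The other lists lay inside the central 95% of random lists for mRNA. TCA cycle genes had a median of −0.14 (percentile 17.985), with IDH3A at −1.23. Translation initiation factors were at −0.05 (17.6), with EIF2B3 at −1.36, and RNA-binding protein genes at 0.06 (57.5). A list of 4 elongation factors (EEF1B2, EEF1D, EEF1G, EEF2) with PABPC1, TPT1, NAP1L1 and HNRNPA1 had a median of 0.13 (44.1), iron handling genes 0.01 (50.1) and mTOR and growth signalling genes 0.16 (82.0), and each of these turned sign under at least 1 of the other scalings. Cholesterol synthesis genes were at −0.16 (17.2). Interferon-stimulated genes were at 0.32 (92.2), although ISG15 was at −1.94. Mitochondrially encoded mRNAs had a median of −0.26 (24.0; 5 of 13 measured), and housekeeping genes 0.22 (76.4). Long non-coding RNAs were at 0.05 (53.1), with a sign that turned under other scalings, CYTOR at 1.66 and MIR22HG at −1.88. Replication-dependent histones were measured for 2 of 16 genes, HIST1H2BK (0.50) and HIST1H1C (0.06). IREB2, an iron-regulatory protein gene, was at 1.67. ACTB, in a shared locus, was at 0.05, a sign that turned under the other scalings.

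**Figure D1:**
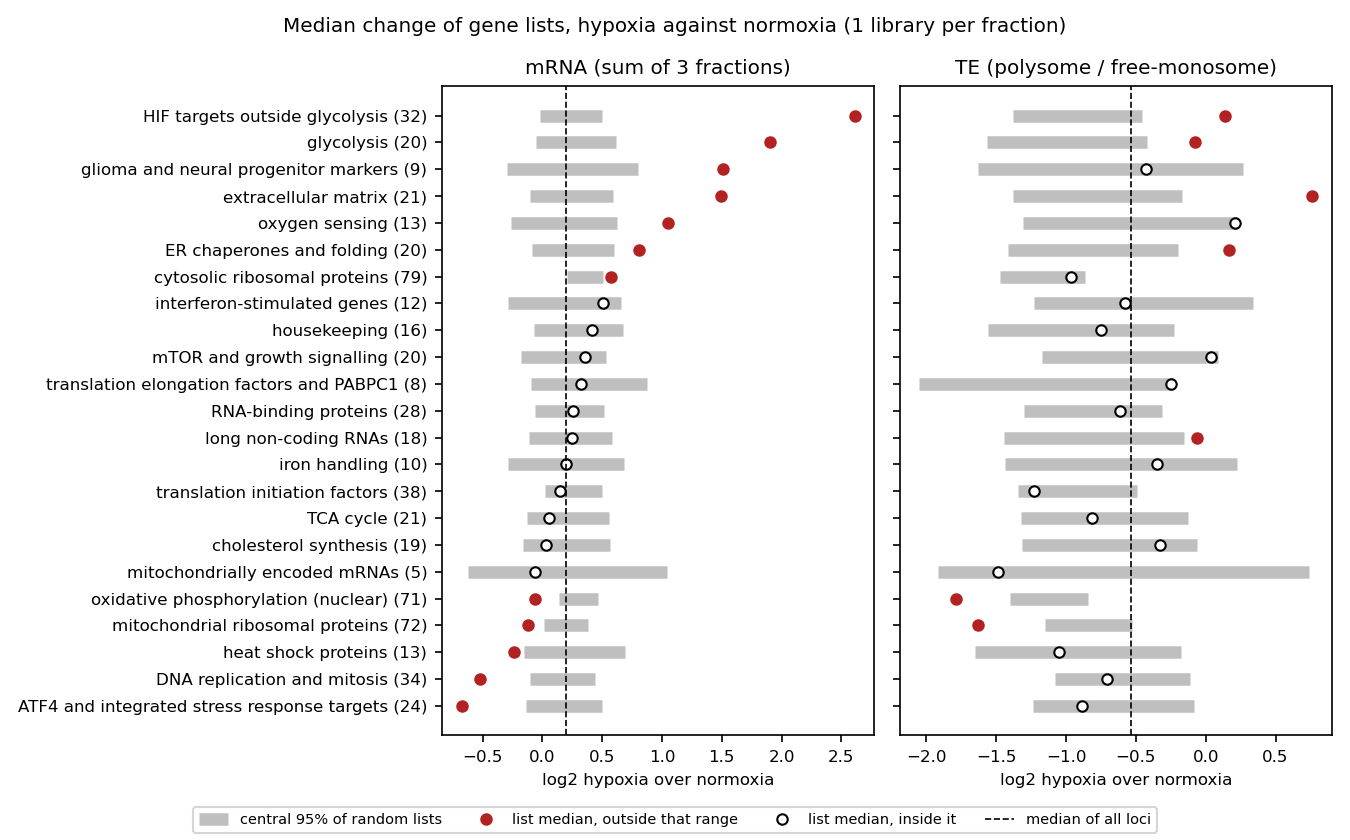
Median log2 hypoxia over normoxia as deposited for 23 gene lists (number of measured genes in parentheses), for mRNA on the left and TE on the right, with the central 95% of random lists as grey bars and the median of all loci (0.20 and −0.53) as a dashed line. HIF targets and glycolysis lie farthest to the right for mRNA, and oxidative phosphorylation and mitochondrial ribosomal proteins farthest to the left for TE; the cytosolic ribosomal protein mRNA point falls inside its bar under other scalings. The list labelled for elongation factors and PABPC1 also holds TPT1, NAP1L1 and HNRNPA1.

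Across all tested loci, 1445 had at least 2-fold more and 654 at least 2-fold less summed mRNA in hypoxia as deposited, so that 68.8% of these were higher. Relative to the median locus the counts were 1004 and 1006, or 49.95% higher. Among those 1445, the ratio was above 1 in all 3 fractions for 1198 (82.9%), and among the 654 it was below 1 in all 3 for 371 (56.7%). Both sets were picked by the sum of these same fractions, so part of this agreement is built in. The signs also depend on the library factors in the deposited values. Over all loci 29.8% had one sign in all 3 fractions, against 18.7% if the signs in the 3 fractions were independent of each other. Across genes, which are not independent replicates, the hypoxia over normoxia ratio of the oligosome libraries had a rank correlation of 0.45 with the free/monosome one and 0.53 with the polysome one, and free/monosome and polysome had 0.20. Besides genes already named, the highest loci were SLC38A5, an amino acid transporter (5.52), the antisense RNA STEAP3-AS1 (4.92) and the adhesion molecule ICAM5 (4.69). Their normoxia sums were low, at 5.19, 4.59 and 2.27 FPKM. The HIPK3 locus (5.94) rested on 1 library, hypoxia oligosome, with 1176 FPKM. The lowest included NTRK3, a neurotrophin receptor (−3.88), AC109925.1 (−3.86, listed at 0 in hypoxia polysome), C12orf57 with RNU7-1 (−3.38), SAC3D1 (−2.69), PKDCC (−2.60), the methionyl-tRNA synthetase MARS (−2.60) and MPV17L2 (−2.58). The DEPDC5 locus, shared with a U6 gene (−5.13), rested on normoxia polysome, with 2871 FPKM.

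For TE, mRNAs of the extracellular matrix and of ER chaperones were placed further toward polysomes in hypoxia than the median locus, and mRNAs of the mitochondrial respiratory chain and mitochondrial ribosome further toward the free/monosome fraction. HIF target mRNAs were placed higher as a list, with single members on both sides of the median locus. Such spread was common: of all 10973 tested loci, 2273 lay at least 2-fold above the median TE difference and 2085 at least 2-fold below. SLC16A3, the lactate exporter, had a relative TE difference of 3.41, and FAM162A, a mitochondrial HIF target, of −2.39. COL6A1 was at 3.25 and the cytochrome oxidase subunit gene COX7B at −2.75.

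Extracellular matrix genes had the highest list median for relative TE difference, 1.30 (percentile 100), with 16 of 21 at least 2-fold higher and 1 lower. Their coding sequences are long (median 4098 nt), and with length matched the list was at percentile 98.8 and its gap to random lists 0.66 in place of 1.59. LAMA4 was at 3.29, COL6A1 (XLOC_038374, chromosome 21, 47401651 to 47424964) at 3.25 and COL5A1 at 3.10, and TIMP2, a protease inhibitor, was at −2.57. LAMA4 had less summed mRNA in hypoxia and still more FPKM as deposited in the polysome library, 82.6 against 52.8. The library's median FPKM as deposited was also higher, 52.8 in hypoxia against 38.4 in normoxia, so part of the LAMA4 difference goes with the scaling. The ER chaperone and folding list had a median of 0.70 (percentile 99.8), with 5 of 20 higher and 2 lower. Examples were HYOU1 (1.99), PDIA4 (1.55) and HSP90B1 (1.43), against HERPUD1 (−1.55) and SEC61B (−1.49), which are not chaperone genes. With length matched this list was at percentile 99.4.

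HIF targets outside glycolysis had a median of 0.67 (percentile 100, or 99.99 with coding length matched), with 12 of 32 at least 2-fold higher and 5 lower. ANGPTL4 had the highest value, 5.67 (XLOC_028927, chromosome 19, 8428173 to 8469326), with 1.03 FPKM in the normoxia and 204 FPKM in the hypoxia polysome library. The prolyl hydroxylase P4HA2 was at 1.92 in a shared locus, CA9 at 1.39, LOX at 1.37 and VEGFA at 0.55. The lower ones included the mitophagy receptors BNIP3L (−1.85) and BNIP3 (−1.54), besides FAM162A. Glycolysis genes had a median of 0.45 (percentile 99.8), with 8 of 20 higher and 1 lower. SLC16A3 was followed by ENO2 (2.05, shared locus) and SLC2A1 (1.69), and the mitochondrial kinase gene PDK1 was at −1.50. PGK1 lay at −0.01, LDHA at −0.35 and GAPDH at −0.37. Against random lists matched on coding length as well, glycolysis was at percentile 92.7, inside the central 95%.

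Of 71 nuclear oxidative phosphorylation genes, 46 had a TE difference at least 2-fold below the median locus and 2 above, with a list median of −1.26 (percentile 0). Among the lowest were COX7B (XLOC_068880, chromosome X, 77154935 to 77162870; −2.75), COX5A (−2.52) and ATP5MC3, in a locus shared with a Y RNA gene (−3.05). NDUFS7 was higher (1.81). COX7B stood at 506 FPKM in the normoxia and 2008 FPKM in the hypoxia free/monosome library, and at 1371 and 559 FPKM in the polysome libraries. Mitochondrial ribosomal protein genes had a median of −1.10 (percentile 0), with 43 of 72 lower and 0 higher, such as MRPL32 (−2.57), MRPS14 (−2.31) and MRPL36 (−2.30). With coding length matched the percentiles were 1.17 and 0.16, both still outside the central 95%. The gap between list and random lists then shrank from −0.70 to −0.30 and from −0.77 to −0.34. Random lists could hold the list's own genes, which by itself narrows the gap. How much of the shrinkage went with coding length alone is thus not known.

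**Figure D2:**
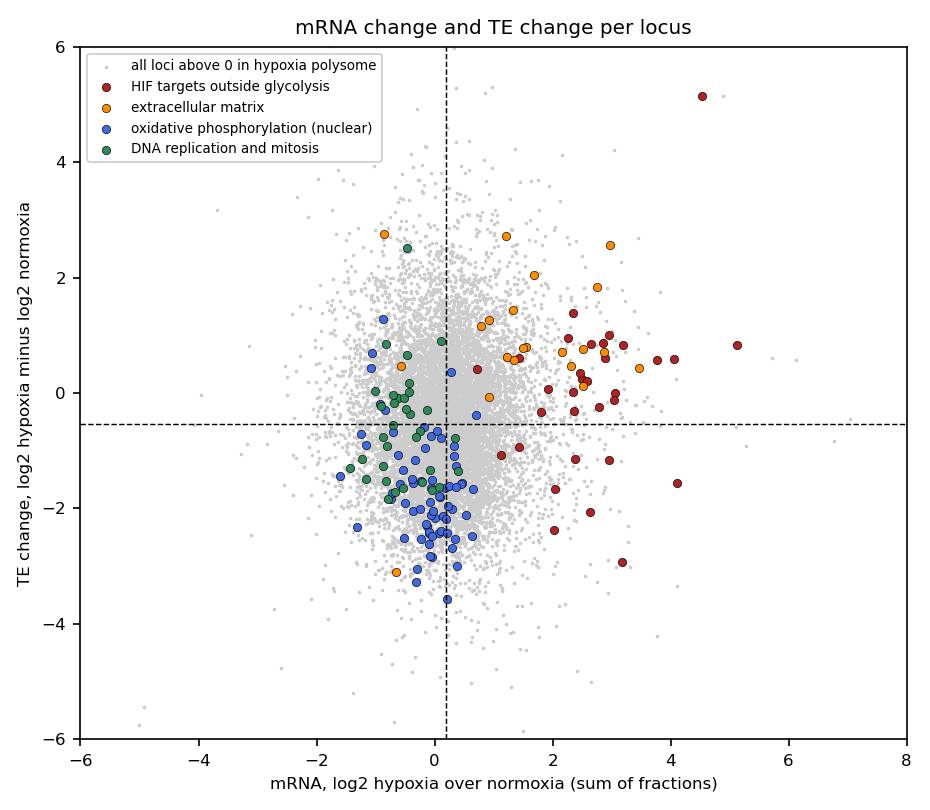
Each point is a tested locus above 0 in the hypoxia polysome library, with its log2 mRNA difference (sum of fractions) on the x axis and its log2 TE difference on the y axis, both as deposited, and dashed lines at the medians of 0.20 and −0.53; some loci lie outside the axes. Most HIF targets (red) and matrix genes (orange) lie to the right, most oxidative phosphorylation genes (blue) low, and most replication genes (green) left of the median.

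Some single regulators of iron and oxygen lay far from the median locus for TE. EPAS1 (XLOC_032053, chromosome 2, 46520806 to 46613839) was at 2.90, with 148 FPKM in the normoxia and 422 FPKM in the hypoxia polysome library, and 189 and 104 FPKM in the free/monosome libraries. FTL, the ferritin light chain gene, was at 2.64 and IREB2 at −1.48. Both EPAS1 and FTL mRNAs carry an iron-responsive element. The iron handling list itself had a median of 0.18 (percentile 75.4, or 54.0 with coding length matched). The oxygen sensing list had 0.74 (percentile 97.1, or 83.4 with coding length matched), with HIF1A at 0.99 and KDM5B at 1.56. Growth signalling genes had a median of 0.57 (percentile 96.7, or 77.35 with coding length matched). The receptor gene IGF1R was at 3.61, TSC2, a brake on mTOR, at 3.26 and RPTOR, an mTOR complex subunit, at 3.11. Coding sequences of IGF1R, TSC2, RPTOR and EPAS1 are long (4101, 5421, 4005 and 2610 nt), and TE differences were higher for longer coding sequences in general.

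Genes of the translation machinery varied. Initiation factors had a median of −0.70 (percentile 7.73), and with coding length matched they were at percentile 0.57. EIF3J (−2.06, shared locus), EIF2S2 (−1.83) and EIF3I (−1.74) were low, and the cap-binding protein genes EIF4E (shared locus) and EIF4E2 were at −1.20 and −1.08. EIF5B was at 0.14. The list of 4 elongation factors with PABPC1, TPT1, NAP1L1 and HNRNPA1 had a median of 0.28 (percentile 97.3, or 82.3 with coding length matched). In it PABPC1, the poly(A)-binding protein gene, was at 2.28. Cytosolic ribosomal protein genes had a median of −0.43 (percentile 88.9, but 100 with coding length matched and 1.495 with TE as polysome over free/monosome + oligosome), with 8 of 79 at least 2-fold higher and 16 lower. RPLP0 (2.29), RPLP1 (1.95) and RPL3 (1.94, shared locus) lay far from RPL32 (−1.88, shared locus), RPL27 (−1.83) and RPL17 (−1.78, shared locus). RNA-binding protein genes were at −0.08 (percentile 80.5), with FUBP1 at −2.31, PCBP2 at −1.95 in a shared locus, HNRNPC at −1.60, HNRNPA2B1 at −0.53, ELAVL1 at −0.24 and PCBP1 at 0.11.

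The remaining lists lay inside the central 95% for TE, apart from long non-coding RNAs (median 0.47, percentile 98.7), whose sign turned when oligosome values entered the numerator. Medians were −0.28 for TCA cycle genes (percentile 45.7), with OGDH at 2.33 and SDHC at −2.12, and −0.35 for ATF4 targets (25.9), with ASNS at −2.11 and ATF4 at −0.30. They were 0.20 for cholesterol synthesis (89.5), −0.17 for DNA replication and mitosis (37.3), where the licensing factor CDT1 was at 3.04, and −0.52 for heat shock genes (39.3). Glioma markers had 0.10 (73.6), interferon-stimulated genes −0.05 (39.5), with IRF7 at 2.49 and OAS1 at −2.13, and housekeeping genes −0.22 (69.9), with PPIA at −2.04 and ACTB at −0.33. Mitochondrially encoded mRNAs had −0.96 (9.92), with 2 of the 5 measured in shared loci. Of these 5, MT-ND1 was listed at 0 in the hypoxia oligosome and polysome libraries, and MT-CYB stood at 0.23 FPKM in normoxia polysome. Whether the ratio reflects translation for these mRNAs was not tested. The 4 measured markers of other cell types ranged from SNAP25 (−0.85) to CSF1R (0.44), and the histone genes HIST1H1C and HIST1H2BK were at −1.84 and −0.55.

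Within each condition, cytosolic ribosomal protein mRNAs had the lowest TE of the protein-coding lists. Relative to the median locus their log2 TE was −3.82 in normoxia and −4.01 in hypoxia (percentile 0 in both), with 79 and 78 of 79 at least 2-fold under it. Long non-coding RNAs were at −3.48 and −3.65 (percentile 0 in both). Matrix genes were at 1.40 and 2.77 (percentile 100 in both) and ER chaperones at 1.26 and 1.86. Across genes the TE of normoxia and hypoxia had a rank correlation of 0.72 (Pearson 0.76).

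**Figure D3:**
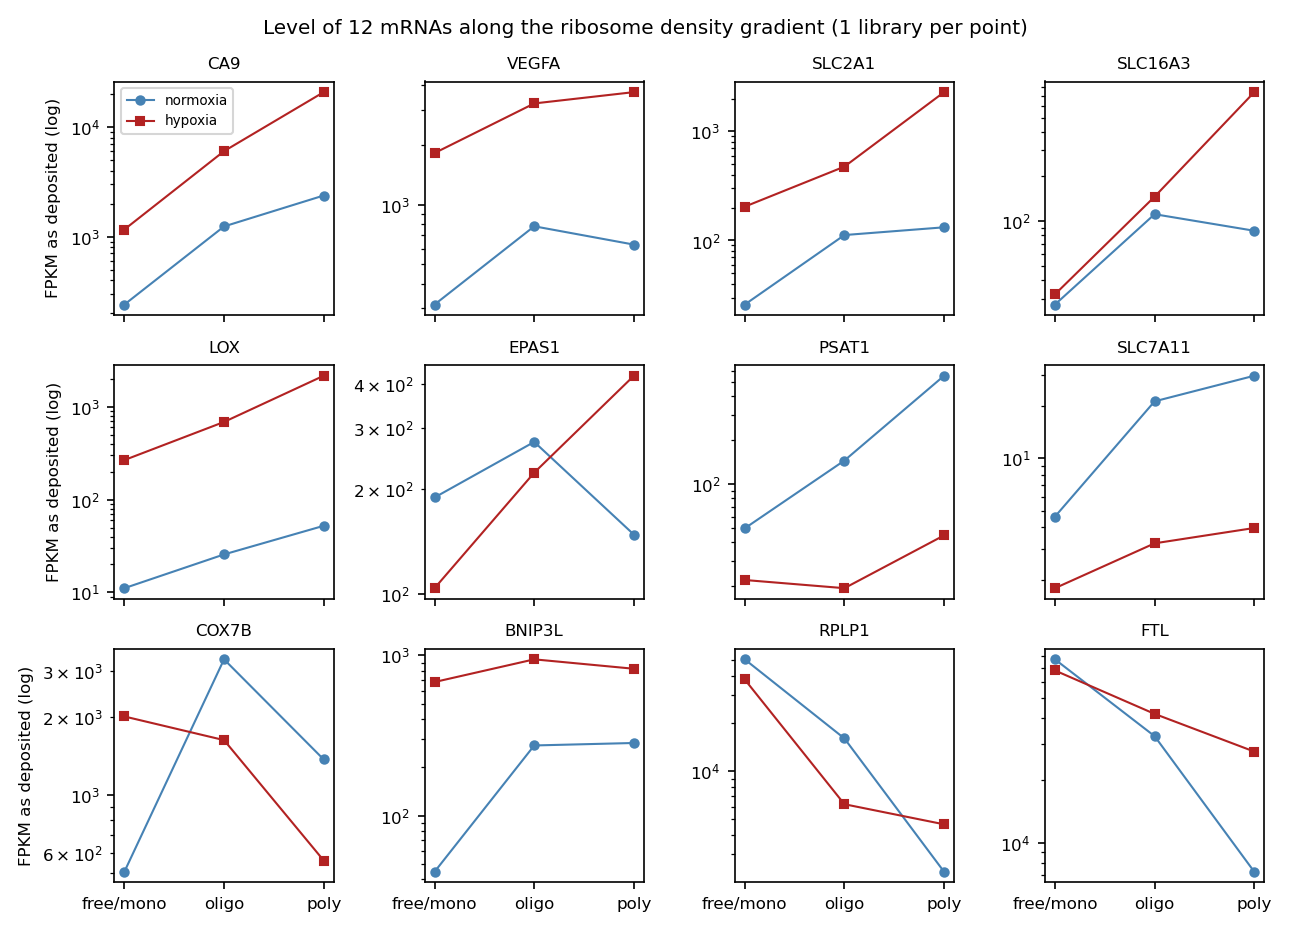
FPKM as deposited (log axis, a separate range per panel) of 12 mRNAs in the free/monosome, oligosome and polysome libraries, normoxia in blue circles and hypoxia in red squares, 1 library per point. For SLC16A3 the polysome point is 86.0 FPKM in normoxia and 742 in hypoxia while the free/monosome points are 27.3 and 32.0; for COX7B the free/monosome point is higher and the polysome point lower in hypoxia.

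As deposited, 1208 loci had at least 2-fold higher TE in hypoxia and 3756 at least 2-fold lower, so that 24.3% of these were higher. This split depends on the definition of TE, since polysome over (free/monosome + oligosome) gave 2787 higher and 483 lower, and on the scaling of the libraries. Counted relative to the median locus, which centres the differences and so brings the split near balance, they were 2273 and 2085 (52.2% higher). The highest loci were NLRP1 with RNU7-31P (11.01), ZNF275 with a snoRNA gene (9.52), PPM1K with a U6 gene (9.39), TRIM66 with a second transcript (7.01), AC007773.2 (6.54), the MIR24-2 locus (5.97), RP5-997D16.2 (5.85), CHPF2 with MIR671 (5.82), ICAM5 (5.68) and ANGPTL4 (5.67). ICAM5 stood at 0.91 FPKM in the normoxia free/monosome and 0.65 FPKM in the normoxia polysome library, near the pseudocount, so its TE difference is uncertain. Of the 10 lowest, 8 were listed at 0 in the hypoxia polysome library, so no fold is given: AC004812.1, AARD, RNY3P8, NID1, RP11-328L11.1, WBP7, MAFF and CCDC141. The others were the KRT18 locus, at 198 FPKM in the normoxia and 1.70 FPKM in the hypoxia polysome library (−8.52), and CTD-2552K11.2 (−5.32). Among the 3756 lower loci, 48 were listed at 0 there.

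The TE difference went with coding length across 8877 loci with a GENCODE coding length, a relation looked at after the data were seen (rank correlation across genes 0.49). TE within a condition had a rank correlation with coding length of 0.15 in normoxia and 0.47 in hypoxia. In 5 length bins the median relative difference was −0.82, −0.33, 0.01, 0.37 and 0.90 from the shortest coding sequences (75 to 747 nt) to the longest (2514 to 26391 nt).

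The mRNA and TE differences were nearly unrelated across genes (rank correlation 0.03, Pearson 0.03). Both share libraries, and with mRNA taken from the oligosome libraries alone the values were 0.00 and 0.01. Scaling moved this correlation to −0.18 with the same median in each library and −0.15 with the factors divided out. Of the 1445 loci with at least 2-fold more mRNA, 394 had a TE difference at least 2-fold above the median locus, as for SLC2A1, CA9 and COL5A1, and 258 at least 2-fold below, as for BNIP3, PDK1 and FAM162A. Of the 654 with less mRNA, 165 lay above, such as NTRK3 (3.71), and 128 below, such as PSAT1 (−1.92) and TRIB3 (−1.91). The NTRK3 value rests on low hypoxia levels, 0.19 FPKM in free/monosome and 1.74 FPKM in polysome.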

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

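Chosen after the results were seen were the tests on the library factors and on a length bias in 1 fraction pair alone, and the normoxia polysome over oligosome values by length; the other tests were written down before their results were seen. Loci without a gene name lay outside the comparisons. Of 623 with a mean of at least 5 FPKM, 176 had at least 2-fold more summed FPKM in hypoxia and 85 at least 2-fold less. Their median length was 558 nt, and their median log2 TE was −1.36 in normoxia and −2.49 in hypoxia.

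For some loci the polysome and free/monosome libraries went opposite ways, by at least 2-fold in each. There were 251 such loci, 93 with more in the hypoxia polysome and less in the hypoxia free/monosome library and 158 the reverse. These counts and their split depend on the library factors. The free/monosome factor was 1 in normoxia and 1.96 in hypoxia, which by itself raises every free/monosome ratio, and the polysome factor was 2.75 and 3.61. The difference between fractions was not tested, since each is a single library. RNY3P8, a Y RNA pseudogene, stood at 336 FPKM in normoxia polysome and was listed at 0 in hypoxia polysome, while its free/monosome log2 ratio was 2.37. NID1, which encodes the basement membrane protein nidogen, stood at 209 FPKM and was likewise listed at 0, with a free/monosome ratio of 2.92. COX7B had a polysome ratio of −1.29 and a free/monosome ratio of 1.99. TSC2 had 1.62 and −1.10, RP5-997D16.2 had 3.34 and −1.98, and AC007773.2 had 2.91 and −3.09, polysome first. All of these ratios are as deposited.

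The first pattern weighed is the surplus of loci with lower TE in hypoxia, 3756 against 1208. With the library factors divided out, lower loci divided by higher loci came to 0.891, but the libraries then have nearly equal medians, which brings the split near balance whatever its cause, so this value does not decide. The surplus also rests on the definition of TE, since polysome over (free/monosome + oligosome) gave 2787 higher and 483 lower on the same values. The polysome over free/monosome factor in hypoxia was 0.669 times that in normoxia because the free/monosome factor was larger (1.96 against 1), whereas the polysome factor held 43.8% of the factor sum against 36.1%, so the factors, if read as RNA amounts, do not show a loss from polysomes. What they stand for is not given in the sources used here, so the scaling and a loss of mRNA from polysomes in the cells cannot be told apart for this surplus.

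The second pattern is the relation of TE difference to coding length, and the low values of mitochondrial genes, many of them short. Matched on coding length, the oxidative phosphorylation list still lay at percentile 1.17 and the mitochondrial ribosomal protein list at 0.16. The gap to random lists shrank from −0.70 to −0.30 and from −0.77 to −0.34. These percentiles argue against length differences between the 10 bins used for matching as the whole cause. Length within a bin was not matched, and the TE difference varied steeply among short coding sequences. Its relative median was −0.82 at 75 to 747 nt and −0.33 at 747 to 1155 nt. The match thus cannot exclude length as the whole cause. A length bias in 1 fraction pair alone is argued against by differences of at least 0.76 in both free/monosome and polysome ratios. Fewer ribosomes per mRNA in hypoxia cannot be told apart from other causes: the oligosome ratio of the shortest bin minus that of the longest was −0.22, and the bound set in advance took a negative value as evidence against it, but in normoxia short mRNAs sat in oligosomes more than long ones did (log2 polysome over oligosome −1.18, against −0.18 for the longest), so a loss of ribosomes would take them out of oligosomes. A regulated response of mitochondrial mRNAs to low oxygen remains a hypothesis, and a length bias of library preparation that acts on several fractions may also contribute.

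The third pattern is the set of 88 loci at least 16-fold from the median TE difference, 18 of them listed at 0 in a library used for TE; without these 18 the shares below were 18.6% and 47.1%. A small RNA gene in the same locus was named for 18.2% of them, against 2.30% of other loci, so it may account for part of the set, such as NLRP1 with RNU7-31P, but not for most of it. A mean under 20 FPKM was seen in 46.6%, against 26.0% elsewhere. Low abundance as the source cannot be told apart from true shifts here, because the share is raised but short of the 50% set in advance and depth is unknown. No biological explanation was tested for this set.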

How the results depend on the processing

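Dividing out the library factors, loci with 1 protein-coding gene name, loci above 0 in every library, mRNA from the oligosome libraries alone and random lists matched on coding length were chosen after the results were seen; the other alternatives were fixed in advance. For mRNA, 12 of 23 lists stood apart from random lists and 8 did so under every alternative run, among them HIF targets (median 2.25 to 2.53 relative to the median locus), glycolysis (1.52 to 1.91), extracellular matrix (0.52 to 1.59), oxidative phosphorylation (−0.58 to 0.023, above 0 without the polysome fraction) and ATF4 targets (−1.13 to −0.42). For TE, 7 of 23 stood apart and 5 did so throughout, namely HIF targets (0.36 to 0.82), extracellular matrix (0.82 to 1.40), ER chaperones (0.24 to 1.05), oxidative phosphorylation (−1.39 to −0.76) and mitochondrial ribosomal proteins (−1.17 to −0.61). Depth is unknown, so how far low values limit these counts was not tested.

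The counts of loci depended on scaling, fractions and thresholds. With a mean of at least 20 FPKM fewer loci were tested, and 410 were lower for mRNA and 739 higher for TE. At 1.5-fold, a looser threshold, the counts were 3069 higher and 1561 lower for mRNA and 2006 higher for TE. With every library at the same median, 2037 were higher and 2330 lower for TE. With the same upper quartile they were 955 and 1046 for mRNA and 2567 and 1755 for TE, and with the factors divided out 2184 and 1946 for TE. mRNA counts were 1393 lower without the free/monosome fraction, 3597 higher and 199 lower without the oligosome fraction, and 1353 lower without the polysome fraction. TE counts were 483 higher with (oligosome + polysome) over free/monosome, 2787 higher and 483 lower with polysome over (free/monosome + oligosome), and 133 and 7425 with oligosome over free/monosome. Beyond the filter and the threshold, the cause was not tested.

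The rank correlation of mRNA and TE differences was −0.18 with the same median, −0.16 with the same upper quartile and −0.15 with the factors divided out. It was 0.33 without the free/monosome fraction, −0.34 without the polysome fraction, −0.13 with the mean of the 3 log2 ratios and −0.073 with polysome over (free/monosome + oligosome). Leaving out a fraction that TE also uses removes a shared library from 1 side, so the sign there follows from the construction; for the scalings the cause was not tested.

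The cytosolic ribosomal protein list had mRNA medians of 0.16 with the same median, 0.058 with the same upper quartile, 0.10 with the factors divided out, −0.48 without the free/monosome fraction and −0.083 with the mean of log2 ratios, each on the other side of the middle of random lists. At a mean of 20 FPKM (0.38, percentile 96.3) and with 1 protein-coding name (0.38, 96.3) it no longer stood apart. Its TE median was −0.71 (percentile 1.495) with polysome over (free/monosome + oligosome), and with coding length matched it was −0.43 at percentile 100. Glycolysis no longer stood apart for TE with polysome over (free/monosome + oligosome) (−0.12) or with coding length matched (0.45, percentile 92.7). Long non-coding RNAs turned for TE with (oligosome + polysome) over free/monosome (−0.67) and oligosome over free/monosome (−0.77). For mRNA, ER chaperones no longer stood apart without the oligosome (0.45, percentile 97.4) or the polysome fraction (0.46, 94.8), mitochondrial ribosomal proteins without the polysome fraction (percentile 19.6) and heat shock genes without the free/monosome fraction (−0.33, 17.6). Some lists stood apart under an alternative alone: 3 for mRNA, all low (TCA cycle, initiation factors, long non-coding RNAs), and 5 more for TE, 3 high (the elongation factor list, growth signalling, TCA cycle) and 2 low (initiation factors, mitochondrially encoded mRNAs). For these lists the cause was not tested.

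Among named loci, mRNA turned sign without the free/monosome fraction for CTD-3252C9.4 with MIR24-2 (0.13), AC007773.2 (0.62), PPM1K with U6 (1.64), RPL12 (−0.61) and TPT1 (−0.15). Without the polysome fraction it turned for the ZNF275 locus (−2.29), the NLRP1 locus (−0.40) and COL6A1 (−0.74), and with the mean of log2 ratios for the ZNF275 locus (−0.23) and COL6A1 (−0.16). TE turned for HIF3A with (oligosome + polysome) over free/monosome (−0.10) and for the HIPK3 locus with polysome over (free/monosome + oligosome) (−5.60). With oligosome over free/monosome it turned for DEPDC5 with U6 (1.14), SLC7A11 (0.075), FABP7 (0.41) and HIF3A (−0.59). NID1 was listed at 0 in normoxia oligosome and hypoxia polysome, so −1.97 for mRNA without the free/monosome fraction and 5.20 for TE with oligosome over free/monosome rest on zeros and are not measured differences. RP11-328L11.1 was listed at 0 in hypoxia polysome, so its turn with oligosome over free/monosome (0.23) is from a value not given. The cause was not tested.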

Other observations

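The tests of the cell surface and mitochondrial carrier families and of cytosolic ribosomal proteins were written down before their results with coding length matched were seen, although percentiles matched on mean FPKM alone were known by then; the other families here were chosen after the data were seen and carry no test of an explanation. Of 6 collagen-modifying enzymes measured outside the fixed lists, 3 had at least 2-fold more mRNA in hypoxia relative to the median locus (list median 1.03, percentile 99.7, or 97.1 and inside the central 95% with coding length matched), and 5 had at least 2-fold higher TE (median 1.78, percentile 100, or 99.93 with length matched). PLOD3, a lysyl hydroxylase, was at 1.17 for mRNA and the highest of the 6 for TE, LOXL3 at 2.18 and 2.04, and LEPRE1, a prolyl hydroxylase of collagen, at 0.89 and 2.15. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, had less mRNA (median −0.58, percentile 0.14), with 6 of 16 at least 2-fold lower. MARS was at −2.60, YARS at −1.63 and VARS at −1.51, while DARS was at 1.67. Their TE median of −0.34 lay inside (percentile 39.7), but at 0.67 with length matched.

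Proteasome loci had a median mRNA difference of −0.55 (percentile 0) and a median TE difference of −0.83 (percentile 0.87, and 0.945 with coding length matched). At least 2-fold lower in TE were 15 of 38 loci, such as PSMD10 (−1.92) and PSMA5 (−1.89), and PSME4, a proteasome activator, was at 1.73. In normoxia their TE was among the highest, 1.38 above the median locus (percentile 100). Spliceosome and Sm protein genes had a TE median of −0.80 (percentile 1.30, or 8.96 with coding length matched), with SNRPG at −2.54 and the large core factor PRPF8 at 3.09. Rab GTPases had more mRNA (0.28) but were inside the central 95% (percentile 97.4, or 99.7 and outside with length matched), and for TE they were at −0.78 (percentile 0.31, or 11.97 with length matched). RAB20 was at 2.99 for mRNA. DEAD-box and DEAH-box helicases (TE 0.37, percentile 91.5), histone demethylases (0.87, 93.8), the vacuolar ATPase (0.10, 89.2) and zinc finger proteins (0.14, 32.0) lay inside for TE, and the COP9 signalosome and mediator (−0.50, 2.73) did too.

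Matrix genes and ER chaperones are made or act at the ER, so a hypothesis was that mRNAs translated there keep a higher TE in hypoxia. A list of 183 loci of cell surface and matrix genes, taken by family symbol, without the fixed lists, had a relative TE difference of 0.75, with 76 at least 2-fold higher and 13 lower. It lay at percentile 99.99 among random lists matched on mean FPKM and coding length, so it may be that translation at the ER goes with the higher values. Examples were LAMB2 (4.13), ITGA3 (3.19) and LRP1 (2.41), while CD55 was at −0.96. Whether these mRNAs sat on the ER was not measured.

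A second hypothesis was that mRNAs of mitochondrial proteins in general are placed lower. A list of 75 loci of carriers and import factors had a TE median of −0.58 (percentile 0.12 matched on mean FPKM alone), with 23 at least 2-fold lower, such as SLC25A4 (−2.81), and 6 higher, such as SLC25A22 (2.12). With coding length matched it lay at percentile 28.1, inside the central 95%, which argues against the hypothesis for this family. Random lists could hold its own genes and other mitochondrial genes, which makes the test weaker. It does not decide what lies behind the low values of the respiratory chain and the mitochondrial ribosome. The mRNA median of the carriers and import factors was −0.46 (percentile 0), with SLC25A33 at −2.70.

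A separate result is the low TE of cytosolic ribosomal protein mRNAs within each condition. With the length of the coding sequence matched, their normoxia TE lay at percentile 0, which argues against length as the whole cause of that low level. It does not bear on their TE difference.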
